A study of Arabidopsis thaliana with 6 samples.

How the data were processed

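Whole-genome bisulfite sequencing was done on DNA of whole seeds at 5 stages and of leaves from Arabidopsis thaliana ecotype Wassilewskija (Ws-0), with 1 library for each of the 6 groups. Bisulfite turns unmethylated cytosine into uracil, which is read as thymine, while methylated cytosine is still read as cytosine. Per the labels' protocols, unmethylated lambda phage DNA was added, and the adapter-ligated DNA went through repeated bisulfite treatment and then PCR. Reads of the lambda DNA were not used here.

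The authors deposited, for each library, the counts of methylated and unmethylated reads at single cytosines of chromosomes 1 to 5, with the strand and the context (CG, CHG or CHH, where H is A, C or T). The deposited methylation fraction of a cytosine equalled methylated over all reads within 0.0001 at every listed cytosine, and was used only for that check. Per the submitters' processing notes the build was TAIR10. The aligner, the caller and the read filters are not given in the sources used here. The values show a filter: in all 6 files no listed cytosine had exactly 1 methylated read or a depth under 2, while cytosines with 0 or with 2 methylated reads were frequent. Of the 38093795 cytosines listed in any library, between 6.41% and 8.74% were absent from a given library. Because that filter depends on the outcome, very low levels are too low, and a level of 0 carries no upper limit here. As an alternative chosen after seeing the data, an absent cytosine was put back with 1 methylated read and the mean depth of the nearest listed cytosine on each side on the same strand, both within 50 bp and with a mean depth of at least 10. Between 71.2% and 84.4% of the absent cytosines of a library were put back this way.

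Gene names, gene extents and gene classes came from a RefSeq gene table of assembly TAIR10.1, whose name differs from that of the files' build. Its register against the files was checked on 625 tRNA genes through a conserved motif of the T loop, read from the positions of cytosines on both strands. The motif stood at its place in 327 genes with no shift, and in at most 1 gene at any shift of up to 5 bp. No coordinates of that table are printed, and all positions given are those of the deposited files (TAIR10, counted from 1). All 119 genes of the 10 fixed lists were found in the table. The table gives no strand, so the planned regions upstream and downstream of genes became the left flank (1 kb at lower coordinates) and the right flank (1 kb at higher coordinates). This departs from the design written beforehand, and a flank can belong to 2 neighbouring genes. Transposable elements were not annotated in the table. Its 3917 pseudogenes, many of which are remnants of transposons in this species, were used as a class of their own. CHH subcontexts, which need the genome sequence, were not analysed here.

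The methylation level of a region is the weighted level, methylated over all reads of its cytosines with a depth of at least 4. Exact (Clopper-Pearson) 95% binomial intervals were computed for levels. They hold no replicate error and take each read at each cytosine as independent. PCR copies and neighbouring cytosines on 1 read are not independent, so the intervals are too narrow even for counting error. The pericentromere was taken as 2 Mb on either side of approximate centromere centres at 15, 3.6, 14, 3.9 and 12 Mb on chromosomes 1 to 5, and the rest as arms. CHH in the bodies of 10 housekeeping genes served as the background for unconverted reads.

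For each pair of libraries, non-overlapping 500-bp windows with at least 5 (CG, CHG) or 10 (CHH) cytosines at a depth of 4 in both libraries were tested. The two-sided exact test of Fisher was applied to the summed methylated and unmethylated reads, with Benjamini-Hochberg adjustment over the windows of a context. Tested differences, and the ranking of named genes, use cytosines covered in both libraries, while a printed level uses all covered cytosines of its library, so differences of printed levels can deviate from tested ones. A window was called at an adjusted p under 0.05 and a difference of at least 30 (CG), 20 (CHG) or 10 (CHH) percentage points. The bodies and flanks of 27444 protein-coding genes were tested in the same way. With 1 library per group such a test compares 2 libraries, not 2 conditions. Its p-values are too small, because cytosines on 1 read are counted separately, and the minimum difference was set for that reason. No p-value was computed across genes, and no difference between conditions has a replicate check. Lists of genes are described by the number of members called and by the percentile of their median among 10000 random lists of genes with similar numbers of cytosines. The random lists were not matched on methylation level, so lists of methylated genes can reach extreme percentiles.

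The test of windows was tested on simulated data drawn at the real depths of global stage and dry seed. Rises of 45 and 60 points in CG and of 30 and 40 points in CHG were recovered in all 67 and 66 planted windows. Rises of 15 and 20 points in CHH were recovered in 66 of 67 and 65 of 66. Planted rises of 15 (CG), 10 (CHG) and 5 points (CHH), below the minimum, gave 0 calls. Unchanged windows gave 0, 1 and 0 calls among 210524, 210777 and 222073 windows. The simulated reads were independent, so this says nothing of reads that cover several cytosines. The planted rises lay well below or well above the minimum difference, which therefore largely decided these outcomes. No falls and no sizes near the minimum were planted.

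Methylation valleys were 5-kb windows, in 1-kb steps, with levels under 5% in each context and at least 50 covered cytosines per context, merged where they touched or overlapped. Most genes named in the text follow a rule fixed before the data were examined, written for upstream regions and applied here to either flank. For each main comparison these were the called flanks whose difference reached the minimum on each strand, taking the 4 largest rises and falls in CG and CHG, the 6 largest rises in CHH and its 4 largest falls. To these came up to 3 called members of each fixed list, or the 2 members listed first where none was called, and the PAI genes and FWA in every library. UBC21, OLEO2, OLEO3, PER1 and the left-flank CHH of MET1 are given outside this rule. Beside a named region, the position given is that of the overlapping called 500-bp window with the largest difference.

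The alternatives were coverage minimums of 1 and 10, unweighted means, the 1% deepest cytosines left out, the 25010728 cytosines at a depth of 4 in all 6 libraries, subtraction of the housekeeping CHH level, windows of 200 and 1000 bp, larger minimum differences, the difference required on each strand, reads thinned to the shallowest library, flanks of 500 bp, other valley limits and each chromosome left out. Further alternatives were added after seeing the data, namely cytosines put back and a neighbouring stage in place of dry or of global stage seed. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and plots matplotlib 3.10.9.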

Results

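Cytosine methylation was compared across seed development in Arabidopsis and between seed and leaf. Whole seeds, which hold embryo, endosperm and seed coat, were collected at 4 DAP (days after pollination; named global stage), 8 DAP (linear cotyledon), 13 DAP (mature green) and 18 DAP (post mature green), and as dry seed from dry siliques. Leaves came from 4-week plants of the same ecotype. Each of the 6 groups was 1 library, so no value has a replicate error. The libraries held between 1156926247 (mature green) and 1484833083 (post mature green) reads summed over cytosines, with mean depths of 33.1 to 42.7 reads per listed cytosine. Between 34764549 and 35650482 cytosines were listed per library. With each read at each cytosine taken as independent, counting error was small at this depth. The widest half-width of a 95% interval was 0.00667 points for genome-wide CG, 0.00402 for CHG and 0.000972 for CHH. The levels of the 2 DNA strands of a library differed by at most 0.143 points in CG, 0.0896 in CHG and 0.0643 in CHH.

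The question for the seed stages was how methylation in each context differed between early and dry seed. CHH methylation, the context without symmetry, was higher in dry than in global stage seed, and the difference lay mainly around the centromeres. The genome-wide CHH level was 0.886% in global stage seed and 2.13% in dry seed, and in the pericentromere 4.25% and 10.4%. In pseudogenes it was 6.14% and 13.5%, against 0.166% and 0.352% in the bodies of protein-coding genes. With cytosines of 1 methylated read put back, the gene bodies had 0.295% and 0.468%. Pericentromeric CG was 62.9% in global stage and 69.1% in dry seed, and CHG 41.4% and 44.9%. In the arms CG was 17.1% and 17.3%, CHG 2.91% and 2.76%, and CHH 0.341% and 0.728%. The arm CG difference of 0.213 points turned to -0.162 as a mean of fractions and to -0.258 with post mature green in place of dry seed, so no direction is drawn for it. That replacement also lowered the pericentromeric CHG difference from 3.46 to 1.78 points, and subtraction of housekeeping CHH lowered the arm CHH difference from 0.387 to 0.209. Both changes, and linear cotyledon in place of global stage seed, also moved the size of the arm CHG difference, which stayed negative. In the 1-kb flanks of genes CG was 13.5% in global stage and 12.5% in dry seed, while CHH was 0.615% and 1.56%. CHH in housekeeping gene bodies, the background for unconverted reads, was 0.0498% in global stage and 0.227% in dry seed. The difference between these values lay mostly in 1 gene, UBC21, a ubiquitin-conjugating enzyme, whose body had 0.535% and 3.89%. Over the other 9 housekeeping genes the level was 0.0229% and 0.0219%. The subtraction used all 10 genes, so the lower arm CHH difference it gave rests mostly on UBC21. Put-back cytosines raised the background to 0.181% and 0.325% for all 10 genes, and to 0.150% and 0.122% for the 9.

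**Figure D1:**
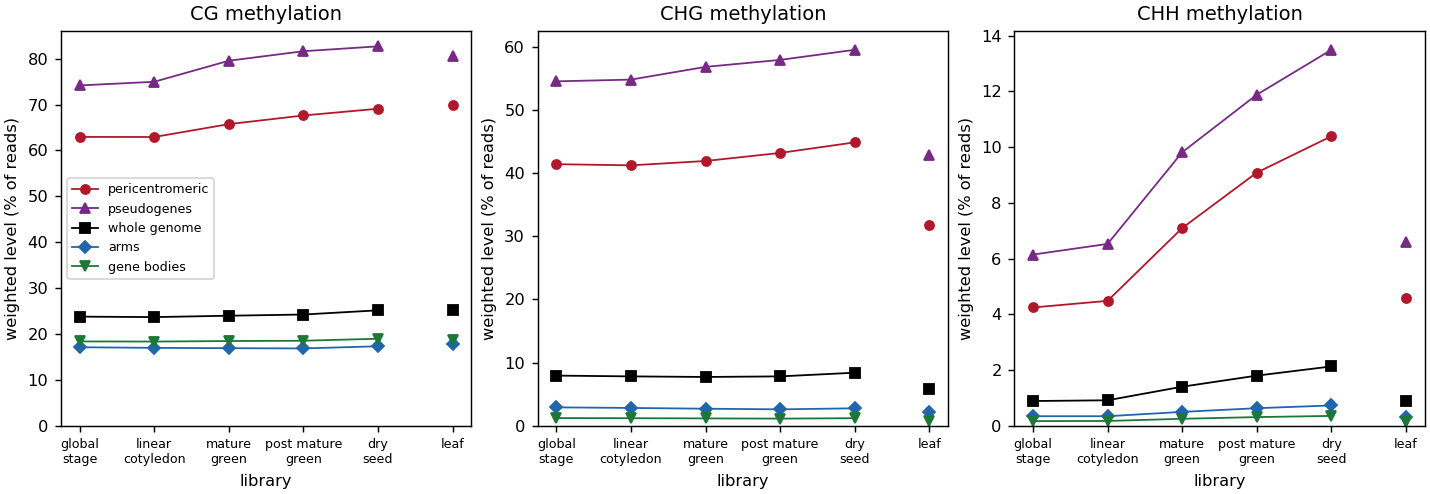
Weighted methylation level (percent of reads, vertical axis) in each of the 6 libraries (horizontal axis) for CG, CHG and CHH, with 1 symbol per part of the genome. Points are single libraries, lines join the 5 seed stages only, and counting intervals are smaller than the symbols. Pericentromeric CHH runs from 4.25% in global stage to 10.4% in dry seed and is 4.57% in leaf, and pericentromeric CHG is 44.9% in dry seed and 31.8% in leaf.

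**Figure D2:**
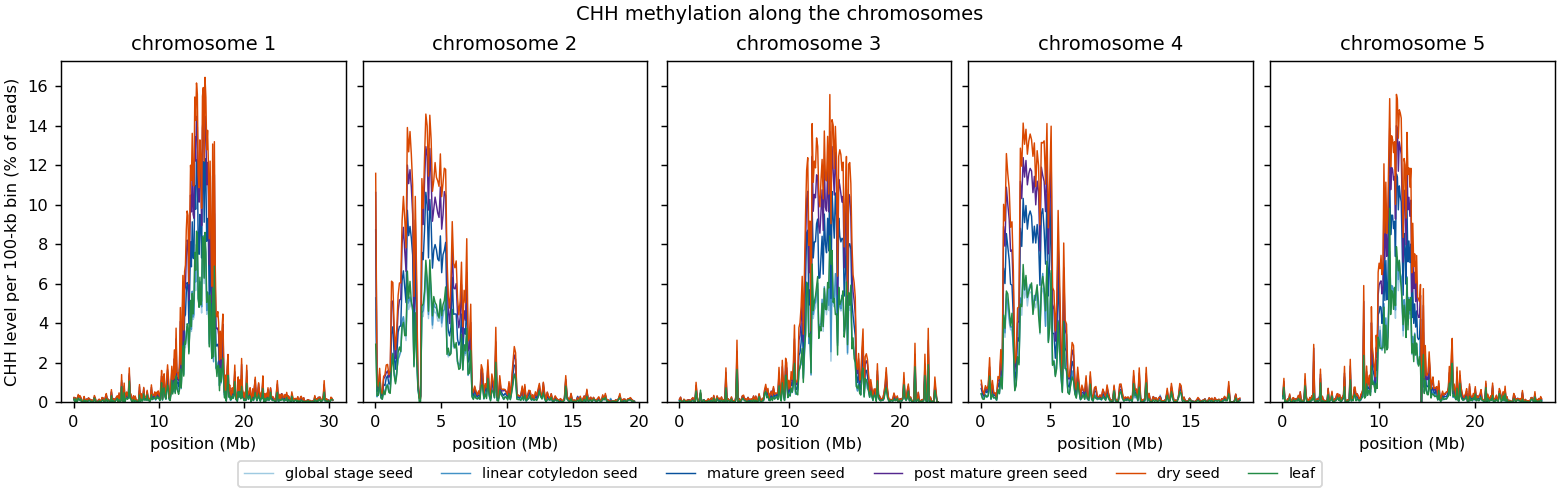
CHH level (percent of reads, vertical axis) in 100-kb bins along chromosomes 1 to 5 (position in Mb, horizontal axis), 1 line per library. The highest levels lie around the centromeres in every library, and dry seed has the highest line there.

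In CHH, 10223 of 222073 windows were higher in dry seed and 16 lower. The windows higher in dry seed made up 17.2% of tested pericentromeric windows and 2.48% of arm windows, 16.6% of windows in pseudogenes and 0.421% of those in gene bodies. In CG the calls went the other way, with 43 windows higher and 276 lower of 210524. The lower ones made up 0.129% of arm windows and 0.146% of pericentromeric windows, and the higher ones 0.00991% and 0.0867%. Lower windows made up 0.270% of windows in flanks of genes and 0.0688% of those in gene bodies. In pseudogenes 8 windows were higher and 4 lower. The pericentromeric CG level was 6.14 points higher in dry seed, less than the minimum difference of a called window. The CG calls therefore do not show the direction of that level. In CHG, 753 were higher and 781 lower of 210777. These are Fisher's exact tests on the reads of 2 libraries. The CHH calls numbered 6731 with cytosines of 1 methylated read put back, and with post mature green in place of dry seed 4512, where CG had 199. Requiring the difference on each strand left 175 CG, 729 CHG and 5227 CHH windows. The CHG split turned to 910 higher and 434 lower with linear cotyledon in place of global stage seed, so no direction is drawn for CHG.

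Near genes, CHH rose from global stage to dry seed in a flank of 856 protein-coding genes and fell at 1, of 27150 tested. Gene bodies had 145 rises and 1 fall. Requiring the difference on each strand left calls at 496 genes in flanks and 77 in bodies. With post mature green in place of dry seed they were at 403 and 56. Beside AT1G03150 the right flank had 9.91% CHH in global stage and 51.1% in dry seed (window at chromosome 1, 759001 to 759500, adjusted p for the flank 5.8e-105). CIPK17, a kinase that binds calcium sensors of the CBL family, had 13.1% and 49.2% in its left flank (chromosome 1, 17813501 to 17814000). BAM1 (AT3G23920), a beta-amylase, had 10.2% and 47.5% in its right flank (chromosome 3, 8645001 to 8645500). The other 3 were AT1G36078 (6.16% and 49.1%), AT1G56080 (5.68% and 46.0%) and AT2G13422 (13.0% and 50.1%). The depth behind these flanks was 106 to 890 reads in dry seed. No CHH fall met the rule for named genes.

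CG fell in a flank of 37 genes and rose at 1, and fell in 7 gene bodies. Calls in flanks were at 20 genes with linear cotyledon in place of global stage seed and at 59 with 500-bp flanks. NOV (NO VEIN), a nuclear protein needed for vein formation, had 54.5% CG in its right flank in global stage seed and 20.7% in dry seed (chromosome 4, 7988001 to 7988500, adjusted p 6.0e-14). LBD27, a transcription factor of the LOB-domain family, had 77.7% and 37.5% (chromosome 3, 17661501 to 17662000). AT3G27320 had 60.3% and 16.96%, and AT1G43145 73.8% over 6 cytosines and 33.0% over 5. No CG rise met the rule. CHG rose in a flank of 96 genes and fell at 159. Among the rises, SEC3B, a subunit of the exocyst that tethers secretory vesicles, had 24.8% and 65.7% in its left flank (chromosome 1, 17466001 to 17466500), and CYCA3;1, an A-type cyclin, 8.47% and 50%, the latter on 52 reads with an interval of 35.8% to 64.2%. AT5G40830 had 33.3% and 70.6%, and AT1G43860 31.5% and 67.1%. CHG falls were at AT3G06436 (65.2% and 19.5%), AT2G24800 (50.8% and 11.4%), AT1G13200 (51.3% and 14.9%) and AT4G24974 (42.8% and 6.63%). With linear cotyledon in place of global stage seed, CHG flanks gave 122 rises and 87 falls. From global stage to dry seed, requiring the difference on each strand left 28 and 92. In gene bodies CHG rose at 3 genes and fell at 47. The body counts were 2 and 34 on each strand, and 7 and 30 with linear cotyledon in place of global stage seed.

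Of the gene lists fixed beforehand, only the genes imprinted in endosperm and the PAI genes had members called between global stage and dry seed. Of the 15 imprinted genes, 2 rose in CHH and 1 fell in CHG, and 12 were not called. SDC, an F-box gene silenced through methylated repeats in its promoter, rose in left-flank CHH from 8.38% to 33.4% (chromosome 2, 7681501 to 7682000, adjusted p 1.1e-89). HDG9, a homeodomain transcription factor, rose from 9.21% to 21.3% (chromosome 5, 5702001 to 5702500). MPC, which resembles the C-terminal part of poly(A)-binding proteins, fell in body CHG from 57.2% to 17.3% (chromosome 3, 6705501 to 6706000). The same 3 genes made up the count adjusted over the list alone, which was 3.

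The 8 other lists had 0 members called by Fisher's exact test with the minimum difference, over all genes and adjusted over the list alone. Over all tested genes, the called shares in flanks were 3.16% in CHH, 0.943% in CHG and 0.141% in CG. In bodies they were 0.542%, 0.187% and 0.0261%. At such low shares, 0 calls in lists this small do not show that these lists were spared. At an unadjusted p under 0.05, without the minimum difference, the members with any region passing were 6 of 14 for storage and oil body proteins, 4 of 10 for LEA proteins and 13 of 15 for seed transcription regulators. They were 9 of 10 for oil synthesis, 3 of 8 for germination, 8 of 12 for photosynthesis, 22 of 22 for DNA methylation and demethylation and 8 of 10 for housekeeping. A member could pass in any of 3 regions and 3 contexts, and these p-values are too small. No share over all genes is given for these unadjusted counts, so they are not a result about the lists. SESA1 and SESA2, which encode 2S albumins, had 0% CG in their bodies in global stage and dry seed, as did EM1, an LEA protein, while EM6 had 0% and 0.223%. LEC1, a master regulator of embryo development, had 56.5% CG in its right flank in global stage and 39.7% in dry seed, and its relative L1L 42.9% and 18.4% in its left flank, where the difference stayed under the minimum. DGAT1, an acyltransferase of oil synthesis, had 14.3% and 13.2% body CG, and the fatty acid elongase FAE1 0% and 0% in its left flank. In the left flank of GA3OX2, a gibberellin oxidase, CHG was 6.03% and 4.65%. The chlorophyll-binding protein gene LHCB1.3 had 20.04% and 16.2% CG in its right flank. For MET1, the maintenance CG methyltransferase, body CG was 25.8% and 28.4%, and for the chromomethylase CMT3 6.06% and 8.73%. The actin gene ACT2 had 2.34% and 3.17%, and UBQ10, a polyubiquitin gene, 16.3% and 11.5% in its right flank. For each gene named so far in this paragraph, 1 of 3 regions and 1 of 3 contexts is shown. The rule for named genes fixed neither, so these values do not stand for the gene as a whole. Median differences of the lists were also set against random lists, in 90 combinations of list, region and context for each comparison, and the following were picked after their values were seen. Body CHH of the imprinted genes had a median difference of 0.0392 points (percentile 100) and body CHG of the DNA methylation genes -0.0972 points (percentile 0.05). PAI bodies had medians of -8.97 points in CG (percentile 0.025), -6.21 in CHG (percentile 0.025) and 6.96 in CHH (percentile 99.96). Because the random lists were not matched on methylation level, these percentiles do not show unusual change for methylated genes. GA3OX1 and LHCB1.1, also first in their lists, stayed under 1% in every region, context and library.

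The second main comparison was dry seed against leaf. CHG and CHH methylation were lower in leaf, and genome-wide CG was 0.111 points higher. That CG value ranged from 0.0297 points without chromosome 2 to 1.02 with post mature green in place of dry seed. Genome-wide CHG was 8.40% in dry seed and 5.84% in leaf, CHH 2.13% and 0.896%, and CG 25.2% and 25.3%. In the pericentromere CHG was 44.9% and 31.8%, and CHH 10.4% and 4.57%. In pseudogenes CHG was 59.6% and 42.8%. Leaf CHG was also below the other 4 seed libraries, which lay between 7.72% and 7.94% genome-wide and between 41.3% and 43.2% in the pericentromere. In the flanks of genes CG was 12.5% in dry seed and 15.2% in leaf. Pericentromeric CG was 69.1% and 69.9%, a difference that changed sign without the deepest 1% of cytosines, as a mean of fractions and without chromosome 3, so no direction is drawn for it.

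In CHG, 10816 of 210700 windows were lower in leaf and 144 higher. The lower ones made up 29.7% of pericentromeric and 1.27% of arm windows, and 35.1% of windows in pseudogenes. In 10472 of the 10816, 96.8%, the leaf level was below all 5 seed libraries, though these windows were chosen for a leaf level under that of dry seed. In CHH, 8520 windows were lower and 6 higher of 221959. In CG, 683 were higher in leaf and 32 lower of 210598. The higher ones made up 0.314% of arm windows and 0.389% of pericentromeric windows. With post mature green in place of dry seed the CHH calls numbered 3720. Requiring the difference on each strand left 423 CG, 5972 CHG and 4340 CHH windows.

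**Figure D3:**
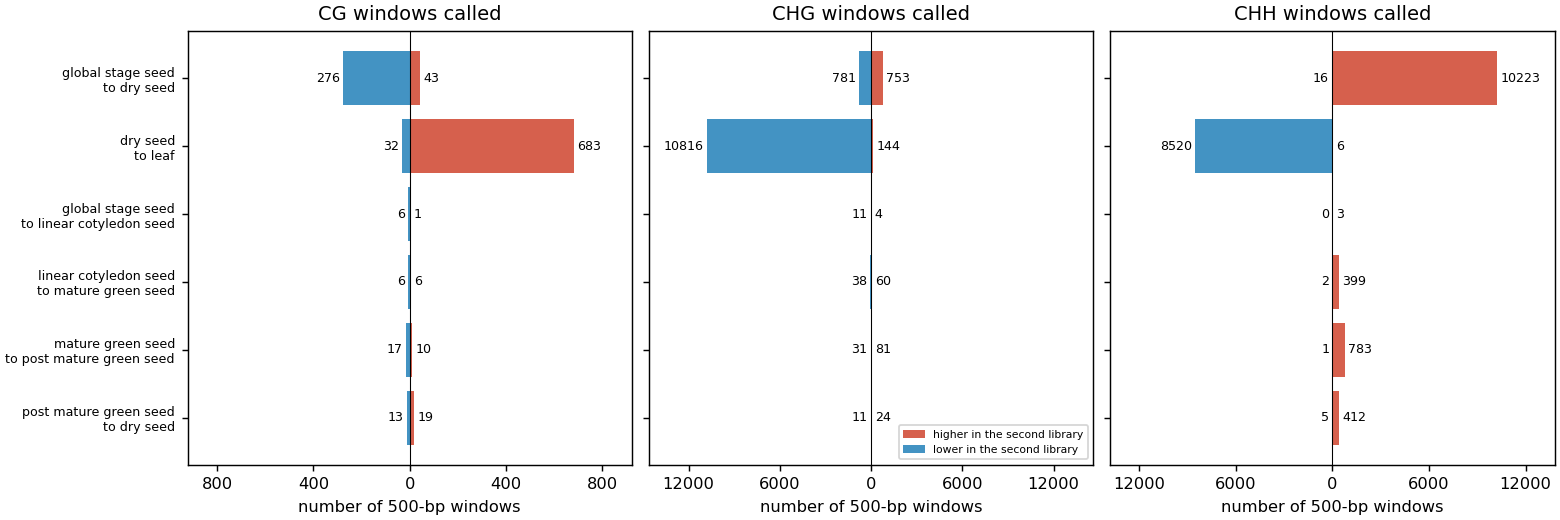
Number of 500-bp windows (horizontal axis) called higher (right) or lower (left) in the second library of each of the 6 comparisons, for CG, CHG and CHH. The scales differ between contexts. CHH has 10223 windows higher in dry than in global stage seed, CHG 10816 lower in leaf than in dry seed, and successive seed stages have at most 784 in a context.

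Near genes, CG rose from dry seed to leaf in a flank of 112 genes and fell at 2, and rose in 22 bodies. On each strand, CG calls were at 57 genes in flanks and 13 in bodies, and CHG calls at 265 and 124. GLDP2, a subunit of the glycine decarboxylase of photorespiration, had 27.9% CG in its left flank in dry seed and 77.8% in leaf (chromosome 2, 11108001 to 11108500, adjusted p 6.0e-53). The other 3 largest rises were at AT5G17470 (17.04% and 70.8%), AT3G27200 (40.8% and 90.8%) and AT2G26780 (27.2% and 75.3%). No CG fall met the rule. CHG fell in a flank of 423 genes and rose at 33, and fell in 206 bodies against 5 rises. The largest CHG falls were at AT3G45210 (62.3% and 17.6%), SYN2, a cohesin subunit (65.2% and 32.5%), AT4G14360 (53.4% and 13.8%) and SEC3B (65.7% and 33.3%). CHG rose in the segment between CAX3, a vacuolar cation exchanger, and AT3G51870, which is a flank of both (27.2% and 71.1%, chromosome 3, 19243001 to 19243500). It also rose at AT3G06436 (19.5% and 54.1%) and at BIR1, a receptor-like kinase of immunity (29.1% and 52.7%).

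CHH fell in a flank of 736 genes and rose at 1, and fell in 138 bodies. Requiring the difference on each strand left calls at 409 genes in flanks and 73 in bodies. Taking post mature green for dry seed gave 295 and 56. The rise was at AT3G06435 (7.29% and 17.9%). The largest falls were at AT1G56080 (46.0% and 7.89%), BAM1 (47.5% and 12.8%), AT1G57850 (38.0% and 4.52%) and CIPK17 (49.2% and 16.7%). At AT1G57850 the dry seed library stood alone on 108 reads, since the other seed libraries had 4.48% to 9.58%.

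Of the fixed lists, 3 had members called between dry seed and leaf. VAL1, a B3-domain repressor of embryonic genes, was the 1 called seed regulator of 15. Its right-flank CG rose from 28.8% to 63.5% (chromosome 2, 12985501 to 12986000) and its left-flank CHH fell from 12.04% to 0.616%. MOD1, an enoyl reductase of fatty acid synthesis, was the 1 called of 10 oil synthesis genes, with left-flank CG of 17.1% and 49.3% (chromosome 2, 2321501 to 2322000). Of the 15 imprinted genes 3 fell, all in flank CHH. They were SDC (33.4% and 8.12%), HDG9 (21.3% and 9.68%) and YUC10, an auxin biosynthesis enzyme (14.4% and 1.44%, chromosome 1, 18094001 to 18094500). The counts adjusted over the list alone were also 1, 1 and 3. The following list medians were picked after their values were seen. For body CHH of the imprinted genes the median difference from dry seed to leaf was -0.0815 points (percentile 0.0), and for body CHG of the DNA methylation genes -0.0779 points (percentile 0.99). PAI bodies had medians of 13.3 points in CG (percentile 99.965), 3.68 in CHG (percentile 100) and -3.61 in CHH (percentile 0.275). The random lists were again not matched on methylation level. The other 7 lists had 0 calls with the minimum difference. Over all tested genes, the called shares in flanks were 2.72% in CHH, 1.69% in CHG and 0.422% in CG. In bodies they were 0.516%, 0.788% and 0.0822%, so 0 calls in small lists do not show that these were spared. At an unadjusted p under 0.05 any region passed in 5 of 14 storage, 5 of 10 LEA, 1 of 8 germination, 5 of 12 photosynthesis, 18 of 22 methylation, 8 of 10 housekeeping and 3 of 3 PAI genes. As in the first comparison, no share over all genes is given for these unadjusted counts.

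Successive seed stages were compared next, and windows were called mainly in CHH and from the linear cotyledon stage on. From 4 to 8 DAP, 3 CHH windows were higher and 0 lower, with pericentromeric CHH of 4.25% and 4.48%. From 8 to 13 DAP 399 were higher and 2 lower (4.48% and 7.10%), from 13 to 18 DAP 783 and 1 (7.10% and 9.09%), and from 18 DAP to dry seed 412 and 5 (9.09% and 10.4%). With cytosines of 1 methylated read put back, the CHH calls of these 3 steps numbered 248, 482 and 311, and with the difference required on each strand 108, 226 and 102. CHG gave 4 higher and 11 lower, 60 and 38, 81 and 31, and 24 and 11 in the same order. CG gave 1 and 6, 6 and 6, 10 and 17, and 19 and 13. The CG splits between 8 DAP and dry seed changed side under several settings and no direction is drawn for them.

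**Figure D4:**
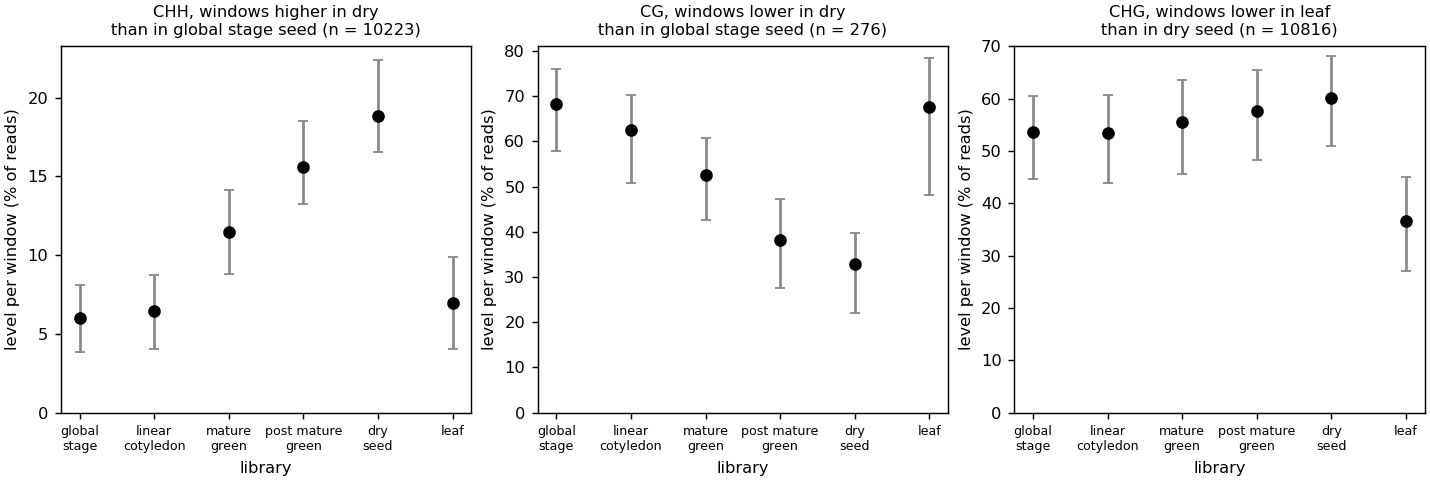
Level per window (percent of reads, vertical axis) in each library (horizontal axis) for the windows called in 3 contrasts. Points are medians over windows and bars run from the lower to the upper quartile, over windows and not over replicates. The 10223 CHH windows have medians of 5.99% in global stage, 15.6% in post mature green and 18.9% in dry seed, and the 276 CG windows 68.3%, 38.2% and 32.8%.

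In the 10223 windows with higher CHH in dry than in global stage seed, the median level was 5.99%, 6.46%, 11.4%, 15.6% and 18.9% over the 5 seed stages in order, and 6.99% in leaf. In the 276 windows with lower CG the medians were 68.3%, 62.5%, 52.7%, 38.2% and 32.8%, and 67.6% in leaf. In these windows the values of global stage and dry seed differ by choice, while those of the other 4 libraries took no part in the choice. BAM1 right-flank CHH was 10.2%, 11.7%, 19.1%, 29.5% and 47.5% in seed, NOV right-flank CG 54.5%, 54.0%, 37.5%, 21.9% and 20.7%, and MPC body CHG 57.2%, 52.6%, 44.2%, 30.8% and 17.3%.

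The PAI genes, which encode phosphoribosylanthranilate isomerase of tryptophan synthesis and are known to be methylated in the Ws ecotype, were methylated in all 6 libraries. PAI1 body CG was 84.4%, 80.8%, 78.6%, 71.9% and 73.7% over the seed stages and 87.8% in leaf, at mean depths of 30.3 to 43.4. Its body CHG was 70.9% in global stage and 45.9% in dry seed, a fall by Fisher's test (adjusted p 4.2e-138), and 60.4% in leaf. PAI2 body CG ran from 86.7% to 77.9% and was 91.1% in leaf, and PAI3 had 79.3%, 80.2% and 79.5% in global stage, dry seed and leaf. Neither was called. PAI1 was thus the 1 called member of 3 between global stage and dry seed, also when adjusted over the list alone. Near-identical copies can share reads, so values of single PAI genes are uncertain. In global stage and dry seed, the mean depth of body CHG was 50.4 and 52.7 for PAI1, against 34.9 and 30.6 for PAI2. Sequence differences between the Ws-0 ecotype and the TAIR10 build were not examined here, and could affect these values and the PAI1 call. FWA, a homeodomain gene silenced in most tissues by methylated repeats and expressed in endosperm, had left-flank CG of 27.9%, 29.9%, 24.2%, 19.5% and 23.7% in seed and 31.6% in leaf. Its body CG was 22.9% in global stage, 18.3% in dry seed and 24.1% in leaf, and no region of FWA was called.

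Much of the genome had little methylation in any library. Methylation valleys numbered 4769 to 4842 per library, and 4725 were shared by all 6 and covered 50.1 Mb. Of the 27444 protein-coding genes 63.9% overlapped a shared valley. The share was 12 of 14 for storage and oil body proteins (percentile 95.3 among random lists of that size), with OLEO2 and OLEO3 outside. It was 9 of 10 for LEA proteins (95.5), with the peroxiredoxin PER1 outside, 13 of 15 for seed transcription regulators (96.7), with L1L and VAL1 outside, and 8 of 8 for germination genes (98.6). Photosynthesis genes had 9 of 12 (78.0), oil synthesis 6 of 10 (39.0), housekeeping 6 of 10 (39.8), DNA methylation and demethylation 12 of 22 (18.8), imprinted genes 7 of 15 (9.13) and PAI genes 2 of 3 (52.0). These percentiles describe the lists and are not tests. With 2-kb windows 10452 shared valleys were found.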

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

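The cytosines put back, post mature green in place of dry seed and linear cotyledon in place of global stage seed were chosen after seeing the data. Each group has 1 library and the labels give no replicate numbers, so no paired analysis was possible and no replicate could be left out. CHH subcontexts were not run. Of the values under alternatives, 182 of those that answer a comparison stayed within their interval or within 1.5 times the count, 209 moved by more than counting error, 78 counts were lower and 19 higher by more than that, and 22 turned direction. Counting error here takes reads as independent and is too small, so the 209 do not measure sampling error. Reads thinned to the shallowest library left all 30 counts within 1.5 times. The cause of these differences was not tested, except that larger minimum differences and the requirement on each strand can only lower a count. Depth limits single flanks with about 100 reads and the lowest levels, where cytosines with 1 methylated read are absent.

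As reported, the CG, CHG and CHH differences from global stage to dry seed were 1.37, 0.458 and 1.24 points genome-wide, 6.14, 3.46 and 6.15 in the pericentromere and 0.213, -0.152 and 0.387 in the arms. From dry seed to leaf they were 0.111, -2.56 and -1.23, then 0.802, -13.1 and -5.82, then 0.505, -0.648 and -0.411. With a coverage minimum of 1, the CG, CHG and CHH differences from global stage to dry seed were 1.38, 0.461 and 1.24 points genome-wide, 6.14, 3.46 and 6.14 in the pericentromere and 0.216, -0.149 and 0.388 in the arms. Leaf minus dry seed gave 0.108, -2.57 and -1.23, then 0.797, -13.1 and -5.81, then 0.504, -0.650 and -0.412. With a minimum of 10, the CG, CHG and CHH differences from global stage to dry seed were 1.353, 0.437 and 1.23 points genome-wide, 6.12, 3.44 and 6.14 in the pericentromere and 0.200, -0.170 and 0.375 in the arms. From dry seed to leaf they were 0.114, -2.53 and -1.22, then 0.828, -13.1 and -5.81, then 0.509, -0.631 and -0.402. As the mean of per-cytosine fractions, the CG, CHG and CHH differences from global stage to dry seed were 0.717, 0.324 and 1.16 points genome-wide, 6.62, 3.52 and 6.30 in the pericentromere and -0.162, -0.0777 and 0.451 in the arms. Leaf minus dry seed gave 0.655, -2.53 and -1.15, then -0.427, -14.2 and -6.12, then 0.840, -0.714 and -0.462. Without the 1% of cytosines with the highest coverage, the CG, CHG and CHH differences from global stage to dry seed were 0.966, 0.252 and 0.961 points genome-wide, 6.72, 3.61 and 6.12 in the pericentromere and 0.112, -0.191 and 0.329 in the arms. From dry seed to leaf they were 0.296, -2.12 and -0.952, then -0.358, -13.9 and -5.87, then 0.487, -0.525 and -0.348. Over cytosines covered in all 6 libraries, the CG, CHG and CHH differences from global stage to dry seed were 2.02, 0.875 and 1.13 points genome-wide, 6.64, 3.95 and 6.64 in the pericentromere and 0.577, -0.0472 and 0.304 in the arms. Leaf minus dry seed gave 0.204, -3.27 and -1.08, then 0.658, -14.7 and -6.02, then 0.669, -0.793 and -0.303. After subtracting housekeeping CHH, the CG, CHG and CHH differences from global stage to dry seed were 1.19, 0.280 and 1.06 points genome-wide, 5.96, 3.28 and 5.97 in the pericentromere and 0.0349, -0.330 and 0.209 in the arms. From dry seed to leaf they were 0.315, -2.36 and -1.03, then 1.01, -12.9 and -5.61, then 0.709, -0.444 and -0.207. The level subtracted was that of all 10 housekeeping genes, whose differences between these libraries lay mostly in UBC21. With cytosines of 1 methylated read put back, the CG, CHG and CHH differences from global stage to dry seed were 1.40, 0.479 and 1.16 points genome-wide, 6.02, 3.45 and 5.48 in the pericentromere and 0.280, -0.132 and 0.363 in the arms. Leaf minus dry seed gave 0.246, -2.32 and -1.17, then 1.28, -12.7 and -5.14, then 0.574, -0.601 and -0.414. With post mature green in place of dry seed, the CG, CHG and CHH differences from global stage to dry seed were 0.459, -0.123 and 0.912 points genome-wide, 4.68, 1.78 and 4.84 in the pericentromere and -0.258, -0.318 and 0.288 in the arms. From dry seed to leaf they were 1.02, -1.98 and -0.902, then 2.27, -11.5 and -4.51, then 0.976, -0.481 and -0.312. With linear cotyledon in place of global stage seed, the CG, CHG and CHH differences from global stage to dry seed were 1.48, 0.583 and 1.22 points genome-wide, 6.15, 3.64 and 5.91 in the pericentromere and 0.344, -0.0558 and 0.387 in the arms. Leaving out each chromosome in turn gave CG, CHG and CHH ranges from global stage to dry seed of 1.255 to 1.53, 0.399 to 0.546 and 1.17 to 1.38 points genome-wide, 5.77 to 6.95, 3.32 to 3.57 and 6.03 to 6.25 in the pericentromere and 0.195 to 0.224, -0.165 to -0.137 and 0.337 to 0.431 in the arms. From dry seed to leaf the ranges were 0.0297 to 0.191, -2.84 to -2.43 and -1.36 to -1.17, then -0.194 to 1.36, -13.4 to -12.9 and -5.92 to -5.68, then 0.446 to 0.525, -0.726 to -0.566 and -0.455 to -0.358.

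As reported, the CG, CHG and CHH windows called numbered 319, 1534 and 10239 from global stage to dry seed and 715, 10960 and 8526 from dry seed to leaf. The 4 successive steps had 7, 15 and 3, then 12, 98 and 401, then 27, 112 and 784, then 32, 35 and 417. With 200-bp windows, the CG, CHG and CHH windows called numbered 1047, 2766 and 26693 from global stage to dry seed and 1752, 20326 and 23011 from dry seed to leaf. In the successive steps the counts were 28, 44 and 8, then 59, 262 and 2100, then 134, 311 and 3464, then 160, 99 and 1330. With 1000-bp windows, the CG, CHG and CHH windows called numbered 63, 464 and 4268 from global stage to dry seed and 167, 5400 and 3403 from dry seed to leaf. The 4 successive steps had 3, 4 and 0, then 5, 18 and 88, then 5, 20 and 167, then 6, 11 and 83. With a coverage minimum of 1, the CG, CHG and CHH windows called numbered 340, 1593 and 10275 from global stage to dry seed and 737, 11087 and 8537 from dry seed to leaf. In the successive steps the counts were 11, 21 and 3, then 17, 104 and 398, then 29, 121 and 786, then 33, 40 and 448. With a minimum of 10, the CG, CHG and CHH windows called numbered 295, 1334 and 10004 from global stage to dry seed and 648, 10317 and 8337 from dry seed to leaf. The 4 successive steps had 3, 15 and 1, then 6, 86 and 390, then 18, 100 and 790, then 34, 29 and 359. With the minimum difference reached on each strand, the CG, CHG and CHH windows called numbered 175, 729 and 5227 from global stage to dry seed and 423, 5972 and 4340 from dry seed to leaf. In the successive steps the counts were 0, 3 and 0, then 2, 41 and 108, then 7, 30 and 226, then 15, 16 and 102. With minimum differences of 40, 30 and 20 points, the CG, CHG and CHH windows called numbered 65, 324 and 1210 from global stage to dry seed and 168, 869 and 958 from dry seed to leaf. The 4 successive steps had 1, 0 and 1, then 0, 6 and 9, then 2, 9 and 26, then 7, 6 and 14. With cytosines of 1 methylated read put back, the CG, CHG and CHH windows called numbered 296, 1470 and 6731 from global stage to dry seed and 658, 10668 and 6091 from dry seed to leaf. In the successive steps the counts were 7, 10 and 3, then 13, 86 and 248, then 24, 101 and 482, then 30, 31 and 311. With post mature green in place of dry seed, the CG, CHG and CHH windows called numbered 199, 976 and 4512 from global stage to dry seed and 558, 8417 and 3720 from dry seed to leaf. With linear cotyledon in place of global stage seed, the CG, CHG and CHH windows called numbered 230, 1344 and 9176 from global stage to dry seed.

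As reported, CG, CHG and CHH calls were at 38, 255 and 857 genes in flanks and 7, 50 and 146 in bodies from global stage to dry seed, and 114, 456 and 737 genes in flanks and 22, 211 and 139 in bodies from dry seed to leaf. With 500-bp flanks, CG, CHG and CHH calls were at 59, 356 and 1021 genes in flanks and 7, 50 and 146 in bodies from global stage to dry seed, and 223, 540 and 897 genes in flanks and 22, 211 and 139 in bodies from dry seed to leaf. With the difference reached on each strand, CG, CHG and CHH calls were at 23, 120 and 496 genes in flanks and 4, 36 and 77 in bodies from global stage to dry seed, and 57, 265 and 409 genes in flanks and 13, 124 and 73 in bodies from dry seed to leaf. With cytosines put back, CG, CHG and CHH calls were at 35, 224 and 674 genes in flanks and 7, 48 and 87 in bodies from global stage to dry seed, and 108, 427 and 588 genes in flanks and 23, 188 and 92 in bodies from dry seed to leaf. With post mature green in place of dry seed, CG, CHG and CHH calls were at 26, 165 and 403 genes in flanks and 6, 39 and 56 in bodies from global stage to dry seed, and 91, 330 and 295 genes in flanks and 12, 156 and 56 in bodies from dry seed to leaf. With linear cotyledon in place of global stage seed, CG, CHG and CHH calls were at 20, 209 and 835 genes in flanks and 4, 37 and 144 in bodies from global stage to dry seed.

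The split of higher and lower turned in several counts, and the cause was not tested. CHG windows from global stage to dry seed were 753 higher and 781 lower as reported. They were 1422 and 1344 with 200-bp windows, 799 and 794 with a coverage minimum of 1, 170 and 154 with the larger minimum differences, and 910 and 434 from linear cotyledon on. CHG flanks were 96 and 159 as reported, 214 and 142 with 500-bp flanks, and 122 and 87 from linear cotyledon on. CG windows from 8 to 13 DAP were 6 and 6, then 31 and 28 with 200-bp windows, 4 and 1 with 1000-bp windows, 9 and 8 with a coverage minimum of 1 and 7 and 6 with cytosines put back. In the other direction they were 2 and 4 at a coverage minimum of 10, 6 and 7 with thinned reads, 0 and 2 on each strand and 5 and 6 with unconverted reads subtracted. From 13 to 18 DAP they were 10 and 17, and 4 and 1 with 1000-bp windows. From 18 DAP to dry seed they were 19 and 13, then 3 and 3 with 1000-bp windows, 7 and 8 on each strand and 3 and 4 with the larger minimum differences. From 4 to 8 DAP CG windows were 1 and 6, and 2 and 1 at a coverage minimum of 10, while CHH windows were 3 and 0, and 4 and 4 with 200-bp windows. Shared valleys numbered 4725 and covered 50.1 Mb as reported, 4176 and 37.5 Mb under 2%, 10452 and 45.6 Mb with 2-kb windows, and 4715 and 49.998 Mb at a coverage minimum of 10.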

Other observations

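The tests of unconverted reads, of the absent cytosines, of very deep cytosines and of the endosperm share were chosen after their results were seen.

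Pseudogenes of different length differed in CHH level. Those under 500 bp had 4.19% in global stage seed, 10.8% in dry seed and 4.36% in leaf, and those over 4 kb 6.60%, 13.96% and 7.15%. Among pericentromeric CG cytosines with a level of at least 50% and a depth of at least 10, the share with a level of at least 90% was 20.5%, 23.5%, 43.6%, 56.3% and 60.0% over the 5 seed stages and 57.1% in leaf. In the arms it was 31.0%, 32.2%, 43.3%, 44.3% and 46.8%, and 60.3% in leaf. MET1, the maintenance CG methyltransferase, had left-flank CHH of 0.699% in global stage seed, 6.28% in dry seed and 2.33% in leaf, and was not called. In the body of UBC21, a ubiquitin-conjugating enzyme, CG was 37.8% in global stage and 26.7% in dry seed, and 43.3% in leaf.

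CHH was higher in dry than in global stage seed. Unconverted reads would raise CHH everywhere, but with cytosines put back the difference was 0.144 points in the bodies of the 10 housekeeping genes, against 5.48 points in the pericentromere. The absence of cytosines with 1 methylated read is argued against for the pericentromeric level only. That difference was 6.15 points before they were put back and 5.48 after. The CHH calls fell from 10239 to 6731 windows, from 857 to 674 genes in flanks and from 146 to 87 in bodies. Those counts thus depend in part on that absence. A single unusual dry seed library is argued against by the post mature green library, which held a median share of 0.729 of the rise (quartiles 0.636 to 0.824). Stage, tissue shares and other differences between the libraries stay open, untested, since each stage is 1 library.

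CG was lower in dry than in global stage seed in 276 windows. In these the post mature green library held a median share of 0.862 of the fall (quartiles 0.729 to 0.957), which argues against a single unusual dry seed library. A changed share of reads of other copies would shift the ratio of dry to global stage depth, which was 0.934 times that of all tested windows. Reads of other copies that map there alike in both libraries leave that ratio as it is and stay open. Stage, tissue shares and library differences stay open as explanations, untested.

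Pericentromeric CG was higher in dry than in global stage seed by 6.14 points. Without the 1% deepest cytosines the difference was 6.72 points, which argues against very deep cytosines. A falling share of endosperm DNA could raise CG, since endosperm DNA has less of it at imprinted genes. Over 18 methylated regions of 11 imprinted genes the median difference was -2.27 points (quartiles -4.70 to 1.16), with 6 regions higher and 12 lower. The median lay under the limit written for arguing against a falling endosperm share, and so met it as written. The test as run also required a negative upper quartile, which the written limit did not state. The upper quartile was positive, so the test was left undecided. The regions are parts of genes and not the pericentromere as a whole, so a falling endosperm share and the stage itself stay open.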
